A study of Pinus elliottii with 16 samples.

How the data were processed

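Data from 16 libraries of vascular cambium RNA from tapped slash pine were used, 4 for each of control and paste at day 5 and day 15, with groups and replicate numbers from the labels. Per the labels' protocols, ribosomal RNA was depleted with a RiboZero kit and libraries were sequenced single-end on an Illumina HiSeq. Per the submitters' processing notes, the tools were FastQC, Trimmomatic 0.32, HISAT2 2.0.4 and Cufflinks 2.1.1. The genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Features that share sequence with a near-identical copy, or overlap another feature, may therefore carry part of each other's fragments.

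The deposited values are a scaled signal, the estimated fragment count of a feature divided by a size factor of the library, as read from the file headers and the values. Low values in each library were close to whole multiples of 1 step, the worth of 1 fragment, of 0.688 to 1.56. Of the values above 0 and up to 20.5 steps, 96.6% to 98.0% lay within 0.1 of a whole number of steps. The sum of a library over its step gives the estimated fragments, 3323980 to 5203910. Because the remaining values are fractional estimates, the values were not treated as counts. The plan written before the data were examined assumed gene counts and a count model. Each comparison was instead tested on a log scale, and the count models planned as main test and alternative were not run.

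Of 8949 features, 1214 were at 0 in every library. The 5856 features with a value of at least 10 in at least 4 libraries were tested. Of the 8949, 125 carried a low-data status in the files, and 34 of these were among the tested. A linear model with 4 group means was fitted to log2(value + 1) over all 16 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance estimation and 12 residual degrees of freedom. The 5 contrasts were paste against control at each day, day 15 against day 5 in each treatment, and the difference of the paste effects. P-values are two-sided and Benjamini-Hochberg adjusted over the features of a contrast, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low features. The labels call the samples biological replicates and speak of 4 randomly chosen trees without tying libraries to trees. P-values therefore measure the spread between these libraries.

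The rule for named features was fixed before the data were examined. It took those past the threshold with no overlap between the 2 groups and a mean log2 CPM of at least 0. Since the files pair no identifier with a description, it allowed the 2 largest rises and 2 largest falls of each paste comparison, and day 15 gave none. One of the 4 has a transcript name in place of a locus identifier and is described as the transcript-named feature. For the same reason the gene lists fixed before the data were examined, which select features by words of a description, could not be run. The list of features called at day 5 was tested at day 15 with limma's fry, which asks whether a list moves on balance 1 way.

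Libraries were compared in pairs over features with at least 20 fragments in both together. The squared deviation from an even split was divided by its binomial variance, and its median by that of a chi-square variable, so that 1 stands for counting noise alone. On simulated libraries this ratio was 1.04 for 2 draws of 1 profile and 25.4 for 2 profiles of 1 group.

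Simulated data had the real depths and, for each feature, its overall mean and its spread pooled over the groups. The fit was tested on these data, in which 200 features were changed in the paste day 5 libraries. For paste against control at day 5, with 5807 features in the fit, it recovered 36.7% of 2-fold, 67.3% of 4-fold, 83.3% of 8-fold and 89.8% of 16-fold changes. Of the 143 features it called, 8 were unchanged ones. At 4 libraries per group most 2-fold changes were thus not recovered in the simulation. The real groups differed in spread, with a median SD of the log2 values of 0.376 and 0.441 in controls at day 5 and day 15. With paste it was 0.554 and 0.654. The simulation also drew noise independently for each feature, while the first principal component of the real libraries took 44.5% of the variance. The simulated rates may therefore not hold for the real libraries.

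Alternatives planned before the data were examined were another scaling (median of ratios), voom weights with library quality weights, no filter, a filter of CPM of at least 1 in at least 4 libraries, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were pseudocounts of 0.5 and 4, library quality weights on the log2 values, scaling to the total and by a trimmed mean, leaving out low-data features, and leaving out the near-identical libraries with and without paste day 15 replicate 3. Figures were drawn with matplotlib 3.10.9. A table of the whole series was not used.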

Results

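RNA was sequenced from the vascular cambium, the dividing layer between wood and bark, of adult slash pine (Pinus elliottii) tapped for resin. All trees had bark stripped. The paste groups then received a stimulant paste on the wound that held sulfuric acid and ethephon, a compound that releases the plant hormone ethylene. The control groups were wounded without paste. Tissue was taken slightly above the wound on day 5 and day 15, with 4 libraries per treatment and day, 16 in all. The deposited tables held 8949 features, each an annotated locus or transcript model, and none was paired with a gene name or description, so features are given by their deposited identifiers and without positions. Expression is given as the normalized fragment count, the authors' estimated count divided by a size factor per library. The libraries held 3323980 to 5203910 estimated fragments, and 6351 to 6901 features were above 0 in a library.

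The first principal component of the log2 values took 44.5% of the variance and the second 13.2%. On the first, paste day 5 replicates 2, 3 and 4 and paste day 15 replicate 3 lay on 1 side, at scores of 36.5 to 106. The other 12 libraries lay between -66.6 and 12.7. Paste day 15 replicate 3 had a mean correlation across features of 0.901 with the paste day 5 libraries and of 0.763 with its own group. Paste day 5 replicate 1 and paste day 15 replicate 1 were nearly identical, with a correlation of 0.986 across features. Over 5293 features their fragment counts differed by 1.66 times the squared difference expected from counting alone. The other 119 pairs of libraries differed by 10.7 to 77.4 times that amount. Both libraries were kept under their labels, and the counts without them are given beside each comparison they moved.

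**Figure D1:**
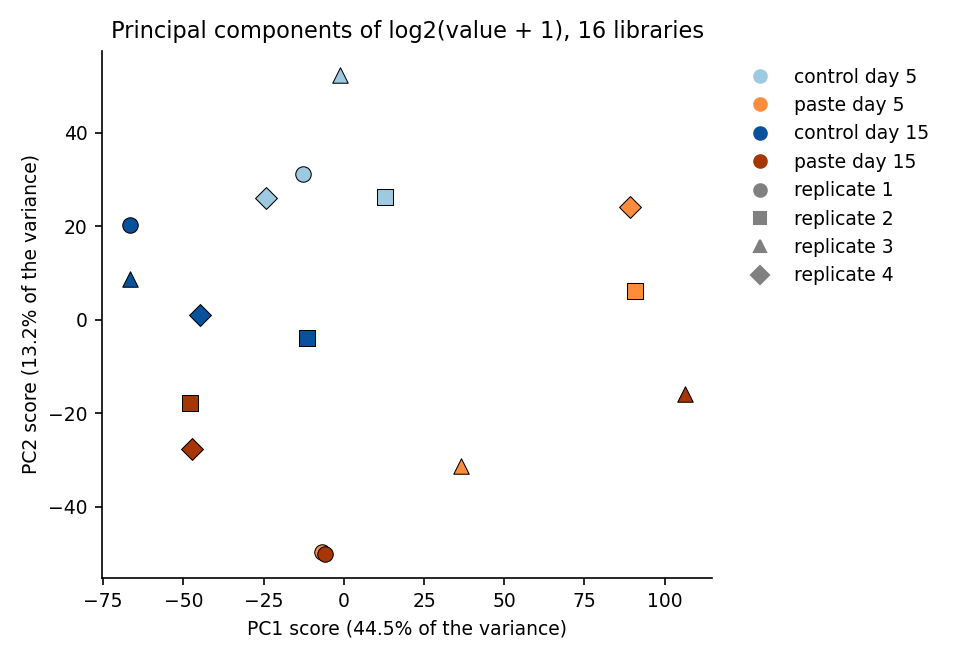
Scores of the 16 libraries on the first (x axis, 44.5% of the variance) and second (y axis, 13.2%) principal components of log2(value + 1) over 5856 features, with colour for group and shape for replicate. The symbols of paste day 5 replicate 1 and paste day 15 replicate 1 overlap, and paste day 15 replicate 3 has the highest first score, 106.

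**Figure D2:**
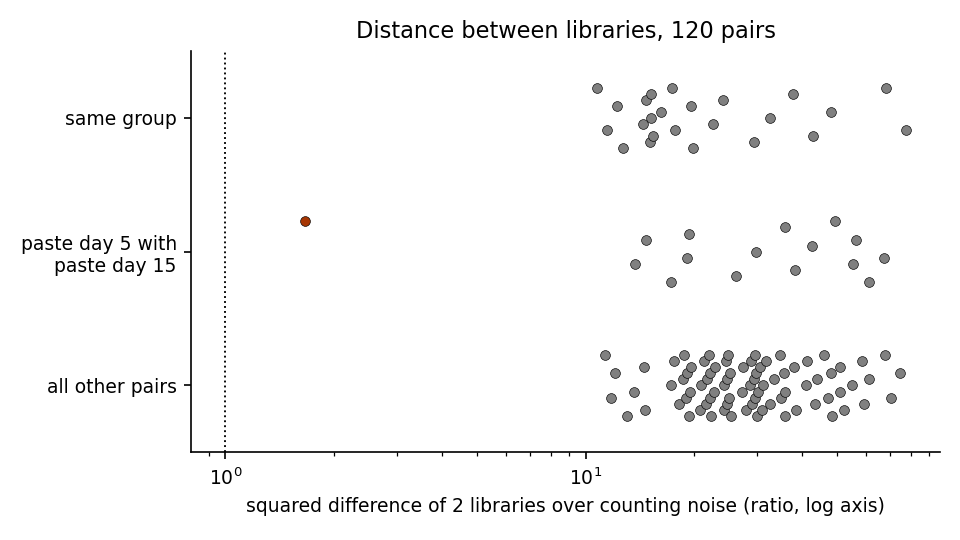
Difference between the fragment counts of 2 libraries as a ratio to counting noise (x axis, log scale), 1 point per pair of libraries, in 3 rows for pairs within a group, pairs of a paste day 5 with a paste day 15 library, and all other pairs. The dotted line marks counting noise alone, and the coloured point at 1.66 is the pair of paste replicates 1.

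The comparison of paste with control at day 5 asked how the whole paste changed cambium expression in wounded trees. No group here received the acid or the ethephon alone, so their parts cannot be told apart. Of 5856 features tested, 37 changed with paste at day 5, 11 higher and 26 lower (limma, Benjamini-Hochberg adjusted p below 0.05, n = 4 per group). PITA_000058385 fell by 6.99 on the log2 scale (SE 0.96, limma adjusted p = 0.00669), about 127-fold. Its normalized count was 7622 ± 4841 (SD, n = 4) in controls and 59.2 ± 40.1 (SD, n = 4) with paste. PITA_000025831 fell by 6.31 (SE 1.32, limma adjusted p = 0.0466), from 383 ± 148 to 6.71 ± 7.33 (SD, n = 4 each). Among the features that rose, one with a transcript name as identifier had a log2 change of 3.85 (SE 0.66, limma adjusted p = 0.0235), from 14.4 ± 5.74 to 310 ± 307 (SD, n = 4 each). PITA_000014344 had a log2 change of 3.80 (SE 0.73, limma adjusted p = 0.0416), from 87.9 ± 36.1 to 1154 ± 283 (SD, n = 4 each). The transcript-named feature was at 755 in paste day 5 replicate 1 and at 54.1 to 239 in the other paste day 5 libraries. Without that replicate its log2 change was 3.23, below the 3.75 of PITA_000014344. Without paste day 5 replicate 4 the log2 change of the transcript-named feature was 4.49 (limma adjusted p = 0.00691).

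The 26 lower features had a median log2 change of -3.63, and their changes ranged from 1.89-fold to 127-fold. The 11 higher features had a median log2 change of 2.99 and ranged from 1.81-fold to 14.4-fold. In all 37 the values of the 4 paste libraries did not overlap those of the 4 controls. Among all features tested, 388 lay wholly above and 380 wholly below control, 13.1% together, where chance gives 2.86%. At an unadjusted p below 0.05 there were 1018 features.

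The day 5 count depended on the fit and on the libraries used. It was 135 with voom weights and library quality weights, 66 higher and 69 lower. A fit of only the 2 groups gave 102, with more higher than lower, 58 and 44. Library quality weights on the log2 values gave 421, 189 higher and 232 lower. It was 18 with no filter on low values, 3 higher and 15 lower. With a pseudocount of 0.5 it was 24, 7 higher and 17 lower. With all groups in the fit it was 8, 10, 8 and 8 without control day 5 replicates 1, 2, 3 and 4 in turn, 12, 7 and 12 without paste day 5 replicates 1, 2 and 3, 18 and 19 without control day 15 replicates 3 and 4, and 14 and 22 without paste day 15 replicates 1 and 4. In those left-out fits 1 to 5 of the calls were higher. The count was 170, 92 higher and 78 lower, without paste day 15 replicate 3, whose spread enters the shared error estimate. Without both near-identical libraries it was 14, 2 higher and 12 lower. Without those and paste day 15 replicate 3 it was 513, 204 higher and 309 lower. With each library scaled to its total it was 41, 18 higher and 23 lower. PITA_000058385 kept its call in all 16 fits that left out 1 library. PITA_000025831 kept it in 3, the transcript-named feature in 10 and PITA_000014344 in 7.

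**Figure D3:**
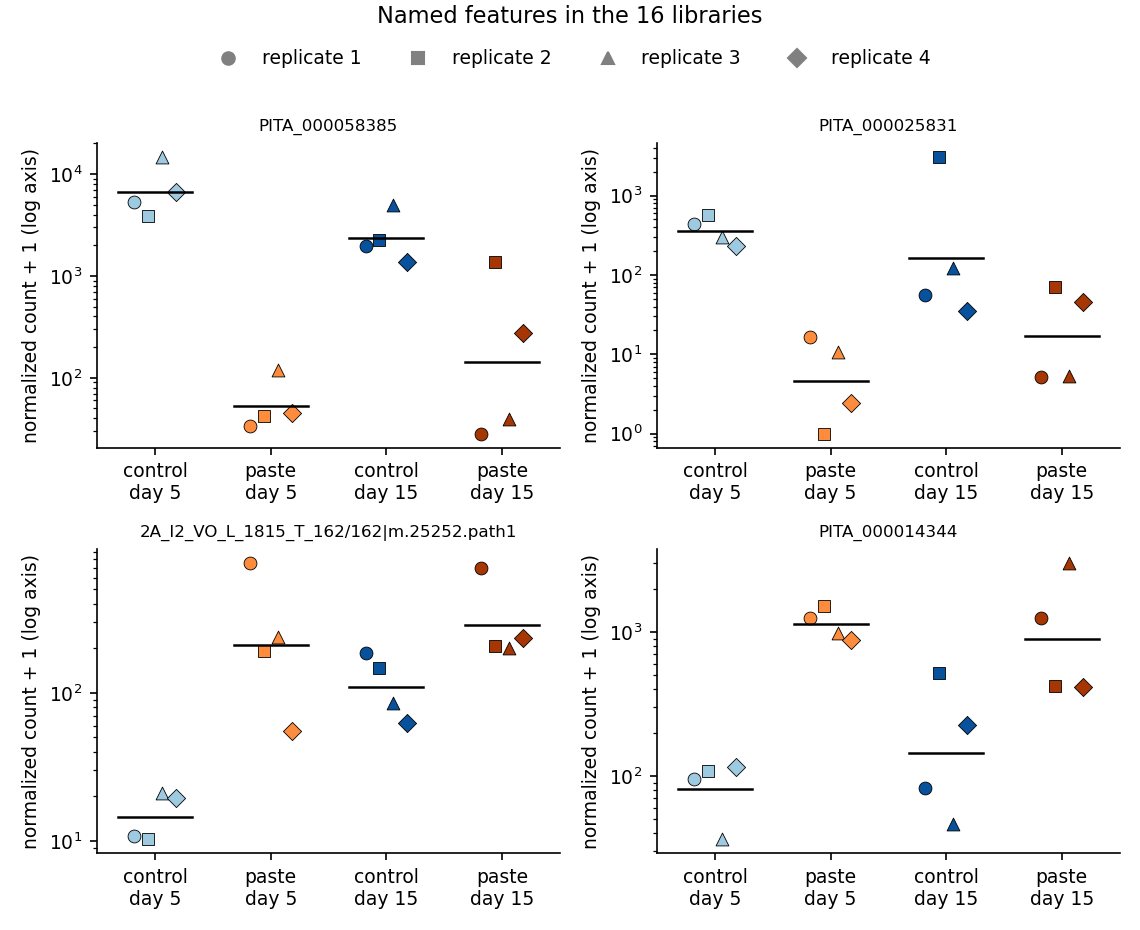
Normalized count + 1 (y axis, log scale) of the 4 named features in the 4 groups (x axis), 1 symbol per library and a line at the mean of log2(value + 1) over 4 libraries. PITA_000058385 lay between 3871 and 14677 in day 5 controls and between 32.8 and 119 with paste at day 5.

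At day 15 the same comparison asked whether an effect of the paste remained. Of the 37 features called at day 5, all 11 of the higher features and 25 of the 26 lower ones had an estimate of the same sign at day 15. Over all 5856 features the share with the same sign at both days was 78.3%. It was 55.1% without the near-identical pair and paste day 15 replicate 3, a choice that itself lowers the share. The median log2 change at day 15 was 1.39 for the higher list and -1.67 for the lower list. As lists, both differed from control at day 15 (limma's fry rotation test, adjusted p = 0.000307 for the higher list and 5.74e-06 for the lower list). The lists were chosen on the day 5 change, with an error estimate that also used the spread of the day 15 libraries. Fry's p-values are therefore not free of that choice. Paste day 5 replicate 1 was also nearly identical to paste day 15 replicate 1. Without paste day 15 replicates 1 and 3, only replicates 2 and 4 were left in that group. The medians were then 0.73 and -1.50, and fry's adjusted p was 0.00683 and 3.3e-05.

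No single feature passed the adjusted threshold at day 15 (limma, 0 of 5856, smallest adjusted p = 0.268), and 539 had an unadjusted p below 0.05. With voom weights and library quality weights the count was also 0, and without paste day 15 replicate 2 it was 1, PITA_000058385, with a log2 change of -5.12 (limma adjusted p = 0.0491). PITA_000058385 averaged 2633 ± 1582 in day 15 controls and 423 ± 631 with paste (SD, n = 4 each), a log2 change of -4.04 (SE 0.96, limma adjusted p = 0.285). Its count with paste was 27.2 and 38.6 in replicates 1 and 3, and 1355 and 273 in replicates 2 and 4. Without paste day 15 replicate 1 its log2 change was -3.26 (limma adjusted p = 0.661), and without replicate 3 it was -3.42 (limma adjusted p = 0.696). PITA_000014344 averaged 218 ± 217 in controls and 1277 ± 1232 with paste (SD, n = 4 each), a log2 change of 2.63 (SE 0.73, limma adjusted p = 0.359). PITA_000025831 averaged 814 ± 1487 in controls and 30.7 ± 32.3 with paste (SD, n = 4 each), a log2 change of -3.26 (SE 1.32, limma adjusted p = 0.497). Control day 15 replicate 2 was at 3044 against 34.4 to 122 in the other controls, and without it the log2 change was -1.86. For the transcript-named feature the log2 change was 1.39 (SE 0.66, limma adjusted p = 0.547), from 119 ± 56.5 to 335 ± 245 (SD, n = 4 each). Features without overlap between the groups made up 3.64%, near the 2.86% that chance gives.

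**Figure D4:**
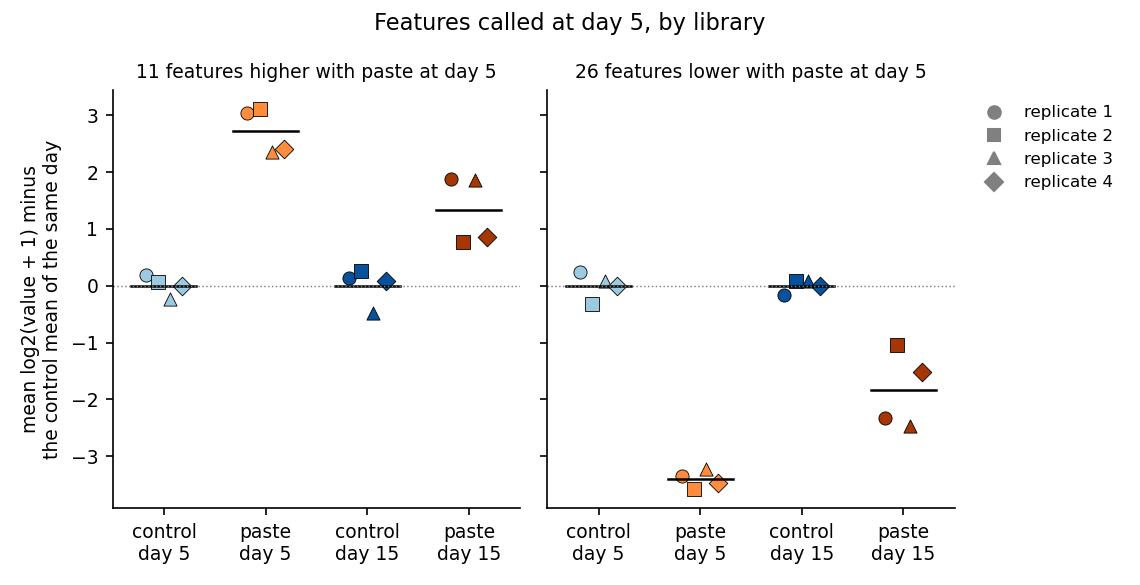
Mean log2(value + 1) of the 11 features higher (left) and the 26 lower (right) with paste at day 5, relative to the control mean of the same day (y axis), in the 4 groups (x axis), 1 symbol per library and a line at the group mean. With paste at day 15 the lower list stood at -2.33 and -2.46 in replicates 1 and 3, and at -1.04 and -1.51 in replicates 2 and 4.

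Across the 5856 features, the log2 changes with paste at day 5 and day 15 had a Pearson correlation of 0.754 and a Spearman correlation of 0.735. Features are not independent replicates, and the 2 comparisons shared no library by label. The Pearson correlation was 0.748 without both near-identical libraries. It was 0.532 without paste day 15 replicate 3, and 0.222 without those 3 libraries. The last value rests on replicates 2 and 4 alone for paste at day 15. Leaving out a library for its likeness to day 5 itself lowers this correlation. With 0 calls at day 15, no overlap of called lists could be counted.

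The difference between the paste effects at day 15 and day 5 was tested directly. No feature passed (limma, 0 of 5856, smallest adjusted p near 1), and 62 had an unadjusted p below 0.05. Those 62 made up 1.06% of features, below the 5% expected if no feature differed. The 0 calls are therefore no evidence that the effects at both days were alike. Voom weights with library quality weights gave 0 as well. For PITA_000058385 the effect at day 15 was less negative by a log2 value of 2.95 (SE 1.36, limma adjusted p near 1). All 37 features called at day 5 had a smaller estimate at day 15, a measure that selection on the day 5 values favours. With the near-identical pair and paste day 15 replicate 3 left out, the test of the difference called 12 features. That count is favoured by leaving out a library for its likeness to day 5. Only replicates 2 and 4 then remained for paste at day 15.

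The change from day 5 to day 15 was compared within each treatment. In control trees no feature passed (limma, 0 of 5856, smallest adjusted p = 0.183), and 585 had an unadjusted p below 0.05. The libraries of the 2 days did not overlap in 13.2% of features, 366 higher and 406 lower at day 15, against 2.86% by chance. A fit of the 8 control libraries alone called 68 features, 32 higher and 36 lower at day 15, and voom weights with library quality weights called 40. The fit without the near-identical pair and paste day 15 replicate 3 called 39. The transcript-named feature went from 14.4 ± 5.74 at day 5 to 119 ± 56.5 at day 15 in controls (SD, n = 4 each), a log2 change of 2.91 (SE 0.66, limma adjusted p = 0.195). PITA_000058385 had a log2 change of -1.51 in controls (SE 0.96, limma adjusted p = 0.628).

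In paste trees no feature passed either (limma, 0 of 5856, smallest adjusted p = 0.819), and 214 had an unadjusted p below 0.05. Those 214 made up 3.65% of features, below the 5% expected if no feature differed. The fit with voom weights and library quality weights also called 0. Leaving out 1 library in turn kept the calls at 0. Features at an unadjusted p below 0.05 then numbered from 55 (without paste day 15 replicate 4) to 1557 (without paste day 15 replicate 3). Features without overlap between the days made up 0.717%, below the 2.86% that chance gives. PITA_000058385 had a log2 change of 1.44 with time (SE 0.96, limma adjusted p = 0.819) and PITA_000014344 of -0.33 (SE 0.73, limma adjusted p = 0.909). The near-identical pair stood on opposite sides of this comparison, which leaves little room for features without overlap. The 2.86% is therefore no fair baseline here. Without that pair the count of calls remained 0, with 460 features at an unadjusted p below 0.05. With paste day 15 replicate 3 also left out, for likeness to day 5, it was 1149, 608 higher and 541 lower at day 15. That choice itself favours a difference between the days, and it left only replicates 2 and 4 in the paste day 15 group.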

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

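The tests of the near-identical pair, of paste day 15 replicate 3 and of the shared error estimate were chosen after those results were seen; the counts over other splits of the libraries were planned before they were run.

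In all, 5 values stood far from the other 3 libraries of their group, out of 36 groups of 4 values examined. Chance gives about 1 in 20 for normally distributed values. The counts of the named features were taken without logs, where far high values are more likely, so that rate need not hold for them. Control day 15 replicate 1 held 3323980 estimated fragments, against 4547990 to 4798480 in the others of its group. In the same library the most abundant feature, PITA_000008841, singled out after its values were seen, took 11.3% of the signal against 3.07% to 3.59%. PITA_000058385 was at 119 in paste day 5 replicate 3 against 32.8 to 44.1. PITA_000025831 was at 3044 in control day 15 replicate 2 against 34.4 to 122. The transcript-named feature was at 701 in paste day 15 replicate 1 against 200 to 233, and at 755 in the nearly identical paste day 5 replicate 1.

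Paste day 5 replicate 1 and paste day 15 replicate 1 differed by a ratio of 1.66 to counting noise, and the next nearest of the 120 pairs by 10.7. A candidate explanation is that 1 RNA sample or library was deposited under both labels. The ratio is what singled out this pair, so it gives that explanation no independent support, and it lies above the 1.04 of 2 simulated draws of 1 profile. A single tree sampled on both days stays open as well: the other 3 paste pairs that share a number across the days had ratios of 29.8 or more, while pairs with different numbers went down to 13.8, but the labels do not tie numbers to trees. No biological explanation was tested.

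Paste day 15 replicate 3 resembled the paste day 5 libraries more than its own group. Scaling is argued against, since its rank correlation, which no scaling changes, was higher by 0.121 with paste day 5 (0.918 against 0.797). A swap of labels with paste day 5 replicate 1 may account for it. That library had a mean correlation 0.049 higher with paste day 15 replicates 2 and 4 than with its own group, but the single correlations overlapped, 0.897 to 0.911 against 0.815 to 0.914, so the swap cannot be told apart from a tree that kept a day 5 state. Among the 35 splits of the 8 paste libraries, the one that exchanges these 2 libraries called the most, 2157 features, where the labelled split called 0; this structure of the samples follows from likenesses already seen, the near-identical pair on 1 side and the library that resembles day 5 on the other, and is no separate support for a swap.

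In control trees no feature was called between the days in the fit of all 16 libraries, while 772 features split the libraries by day. The wider spread of the paste libraries in the shared error estimate is a possible explanation, since the fit of the 8 control libraries alone called 68. The splits argue against chance for both counts but cannot exclude it. Of the 35 splits of the control libraries only 1, the labelled one, gave as many, which is the lowest share they can give. The highest others gave 416 features without overlap and 4 calls. Both counts come from the same 8 libraries. Time after wounding and the conditions of the 2 sampling dates coincide, so the source of this difference was not tested.

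For paste against control at day 5, the splits argue against chance but cannot exclude it. The labelled split called 37 features, and the highest other called 0. Only 1 of 35 splits, the labelled one, gave as many, and 1 of 35 is the lowest share that these splits can give. A count of 0 is reached by any split, so for the other comparisons the splits say nothing about chance. The highest count of another split was 0 at day 15, 1 between the days in control trees and 2157 in paste trees, over 35 splits each, and 29 for the difference of the paste effects over 100 relabellings. For the correlation of 0.754 between the paste effects, 1 of 100 relabellings within days, the labelled one, was as high, and the highest other gave 0.642.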

How the results depend on the processing

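The direction of all 4 named features held under every alternative. These features were chosen for no overlap between the groups, which all but fixes their direction, so this is no sign of robustness. PITA_000058385 kept its call throughout, with log2 changes of -7.03 to -6.42 over 14 alternatives. Of those 14, PITA_000025831 kept its call in 7 and PITA_000014344 in 11. For paste against control at day 5, against 37 calls, voom weights with library quality weights gave 135, no filter 18, only the groups compared 102, and the replicate block 21. Settings chosen after seeing the data gave 24 with a pseudocount of 0.5, 421 with library quality weights on the log2 values, 14 without both near-identical libraries and 513 without those and paste day 15 replicate 3. Leaving out 1 library gave 7 (paste day 5 replicate 2) to 170 (paste day 15 replicate 3), and all 37 were among the 170. For day 15 the range was 0 to 1 (paste day 15 replicate 2), for the 2 time comparisons and the difference of effects it was 0 throughout. With the replicate block day 15 had 3 calls, all lower, and the counts of 0 in the other comparisons did not change. Replicate numbers were not taken as pairs, since 10 of 24 same-number pairs, not all, had correlated deviations over 0.1 (a mean of 8.98 with numbers shuffled within groups). As a hint from the data, 8 of 16 libraries correlated best with their own number, against a mean of 4.04 in 10000 shuffles, 6.64% of which gave 8 or more.

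Day 15 against day 5 in control trees gave 40 calls with voom and quality weights, 68 in controls alone, 125 with library weights and 39 without the 3 doubted libraries, against 0. Without those 3, and so with only replicates 2 and 4 for paste at day 15, paste trees gave 1149 calls, against 0. The difference of effects gave 12, also against 0. Since paste day 15 replicate 3 was left out for resembling day 5, these 2 counts are favoured by that choice. The correlation of the paste effects, 0.754, was 0.212 without those 3 among the features then tested, and 0.535 to 0.774 with 1 library left out. The same choice itself lowers this correlation. Scaling to the total put the median log2 change with time in paste trees at 0.14, against 0.02. Beyond the libraries left out, the cause of these moves was not tested. The planned count models were not run, because the values are scaled and not whole counts.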

Other observations

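The test of spread was chosen after the result was seen; the test on separate control libraries was fixed before it was run.

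Of the 37 features called with paste at day 5, 36 had an estimate of the same sign for day 15 against day 5 in control trees, a comparison in which none of them passed the threshold. The agreement of signs could mean that control cambium moves with time towards the state that paste gave at day 5. Both measures use the same day 5 controls, however, whose chance values push them the same way. When features were chosen anew with 2 of the day 5 controls and the change with time was taken from the other 2, a mean of 55.4% of 37 features went the same way over the 6 ways to divide the controls, with a range of 45.9% to 64.9%. Per division, 13 to 21 lower features and 1 to 4 higher features went the same way, so the pooled share need not hold for each direction. The features chosen anew also need not be the 37 called ones. By the rule fixed before the run, a mean share this low counted against that hypothesis. Higher and lower features differed, however, so the test does not decide on it. Shared controls remain a candidate source of the 36.

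Libraries of a paste group correlated less with each other than those of a control group. The mean correlation across features was 0.879 at day 5 and 0.840 at day 15 with paste, and 0.930 and 0.903 in controls. A wider response to paste between trees may be one reason, but the difference of -0.057 had an exact two-sided permutation p of 0.161 over 4900 relabellings within days, so the hypothesis stays open. The day 15 part rests on paste day 15 replicate 3, without which the paste mean was 0.916, above the control mean of 0.903. At day 5 the paste mean stayed between 0.859 and 0.903 with any 1 paste library left out, below the control mean.

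Identifiers came in 3 forms. Of the 37 features called at day 5, 29 began with PITA_, 5 with PITAhm_ and 3 had transcript names, from 4004, 1363 and 489 tested, and no form was over-represented (Fisher's exact test, smallest adjusted p = 0.326).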
